A study of Mus musculus with 12 samples.

How the data were processed

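RNA from mouse primary myotubes was sequenced in 12 stranded total RNA libraries, per the labels' protocols. Each library has 1 column in a table of 20201 genes. The values are a signal that the authors deposited as normalized counts: per the submitters' processing notes, reads were trimmed with Trimmomatic 0.33, aligned to mm10 with STAR 2.5.2, counted with RSEM 1.3.3 and normalized with DESeq2. The gene annotation used for counting is not given in the sources used here. RSEM shares reads that fit several genes among them by estimate, so levels of genes with near-identical copies are uncertain.

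The deposited values were found to be whole reads divided by 1 factor per library. Dividing each column by its smallest value above 0 gave whole numbers for 100% of values within 1e-06 reads, and size factors recomputed with DESeq2 1.42.0 on these reads equalled the deposited ones (ratio 1 in all 12 libraries). The recovered reads therefore are expected counts rounded before normalization. They totalled 6376584 to 12463339 per library. A few genes took most of them: Gm42418, a non-coding gene (chromosome 17, 39846958 to 39848788, mm10), took 1.33% to 43.7%, and ENSMUSG00000045999, which GENCODE M21 does not name, took 0.436% to 42.3%. Together with Lars2, a coding gene, mitochondrial ribosomal RNA and other non-coding RNA genes, these 11 genes made up 50.5% to 66.2% of reads, which lowers the depth for all other genes. A floor of 3 reads corresponded to 2.12 to 5.85 normalized counts, and such floors cover counting error only. The design was written for normalized values and was kept after the reads had been recovered.

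Identifiers were named from GENCODE M21 (GRCm38, which is mm10), which held 19970 of the 20201 (98.9%). All 12 columns matched a sample title. Groups were taken from the genotype and treatment labels, 6 libraries each, and replicate numbers follow accession order and pair nothing. No pair of libraries was alike within sampling noise: the smallest chi-square per degree of freedom between 2 libraries was 5.33.

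Choices made before the data were examined were the groups, the tests, the gene lists, the rule for named genes and most of the alternative settings. The main test was limma 3.58.1 with a trended prior on log2(normalized count + 1), two-sided, with Benjamini-Hochberg adjustment over 12553 genes with a mean of 10 or more. Another 7648 genes lay below that minimum. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The label-check genes were compared with exact permutation tests over all 924 relabellings, adjusted over 11 genes. The 33 gene lists were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 32 lists with measured members. Members were counted by the adjusted p over all genes and adjusted over the list alone.

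The named genes were Arntl and all measured clock genes, the 10 largest rises and 10 largest falls among called genes with a mean of 50 or more (predicted genes, pseudogenes and mitochondrial ribosomal and transfer RNA left out), and up to 2 risers and 2 fallers per list that is not a marker list, or the most abundant member where none was called. This gave 100 genes, of which the text names the greater part.

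The steps were tested on simulated data, with 200 of 12553 genes changed. For the labelled knockout against labelled wildtype comparison, 39% of the genes changed 1.5-fold and 84% of those changed 2-fold were recovered, 6 calls (4.65%) were false, and 0 of 20 random lists were called. Genes were drawn independently of each other, and no sets of libraries within a label were built in. The simulation therefore does not test the list calls on correlated genes, such as ribosomal protein genes (estimated correlation 0.81).

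Alternatives were other pseudocounts (0.5 and 10), other filters, median-of-ratios, upper-quartile and quantile scaling, robust and library-weighted fits, an exact rank test, a fold threshold, edgeR 4.0.16 (quasi-likelihood) and DESeq2 on the recovered reads, and each library left out in turn. On the recovered reads edgeR called 2407 genes and DESeq2 called 2844. Chosen after seeing the data were leaving out the 11 abundant genes, thinning to a common depth of 2253669 reads outside them, and removing the trend with transcript length and GC content from each library. No library was left out of the main test, and no library was regrouped. R 4.3.3 and Python 3.11.15 were used.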

Results

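RNA sequencing was carried out on mouse myotubes, the multinucleated muscle cells that form when cultured myoblasts fuse. The myoblasts came from mice with a floxed Bmal1 gene. Bmal1, listed here under its older symbol Arntl, encodes the circadian transcription factor that activates clock-controlled genes together with CLOCK. Myotubes received an adenovirus with the Cre recombinase, which excises the floxed part, or an empty virus for 48 hours, and were then kept in 21% or 1% oxygen for 6 hours. The design text describes 4 conditions, whereas the sample labels give 2: 6 libraries labelled wildtype with 21% oxygen and 6 libraries labelled Bmal1 knockout with 1% oxygen. Genotype and oxygen therefore go together in the labels, and only their joint contrast was compared. The labels name no culture, animal or batch, so the p-values measure the spread between these libraries, which may be technical. The libraries held between 6376584 and 12463339 recovered reads.

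The first question was whether the targeted gene followed the labels. Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126, plus strand, mm10) lay at 133 to 179 normalized counts in the libraries labelled wildtype and at 41.7 to 48.6 in those labelled knockout. The means were 157 ± 19.3 and 44.7 ± 2.85 (SD, n = 6 each), a log2 difference of -1.78. This was past a two-sided exact permutation test over 924 relabellings (p = 0.00216, the smallest they can give; adjusted p = 0.00595 over the 11 label-check genes). Nr1d1 and Dbp, direct BMAL1 targets, and Per3, a clock gene, were lower in all 6 libraries labelled knockout than in any labelled wildtype. Their log2 differences were -3.42, -1.31 and -1.87, each with the same exact permutation p. Ciart, another clock gene among the label-check genes, did not follow the genotype label (log2 difference 0.65, exact permutation p = 0.71, adjusted p = 0.819). The genotype label was thus matched by Arntl in all 12 libraries, though not by every clock gene checked.

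The oxygen label was not matched by the genes that low oxygen induces. Egln3, a prolyl hydroxylase gene and target of the hypoxia-inducible factor HIF, stood at 270, 243, 241, 2218, 2258 and 2199 normalized counts in wildtype replicates 1 to 6, labelled 21% oxygen. It stood at 262, 194, 202, 2036, 2056 and 2143 in knockout replicates 1 to 6, labelled 1% oxygen. Slc2a1, the glucose transporter gene, stood at 553, 475, 521, 3457, 3514 and 3487 in the former and at 581, 588, 549, 3168, 3337 and 3554 in the latter. Neither gene differed between the labelled groups by the exact permutation test (log2 difference -0.15, p = 0.595 for Egln3; 0.05, p = 0.745 for Slc2a1; adjusted p = 0.818 and 0.819). Vegfa, Ankrd37, Pdk1 and Car9 did not pass the exact permutation test either (p = 0.578, 0.574, 0.571 and 0.864). Over the 39 measured genes of the hypoxia list, 1 rose, 1 fell and 37 did not pass, with the same counts adjusted over the list alone. The list was not called by camera (adjusted p = 0.739), but with library weights it was, as lower in the libraries labelled knockout (mean log2 fold change -0.57, adjusted p = 0.0492), against the oxygen label. The mean log2 level of the list was 8.16, 8.13, 8.11, 9.89, 9.87 and 9.89 in wildtype replicates 1 to 6, and 8.18, 8.17, 8.10, 9.87, 9.91 and 9.91 in knockout replicates 1 to 6. The groups are therefore called by their labels throughout, no library was moved, and no difference below is attributed to oxygen.

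**Figure D1:**
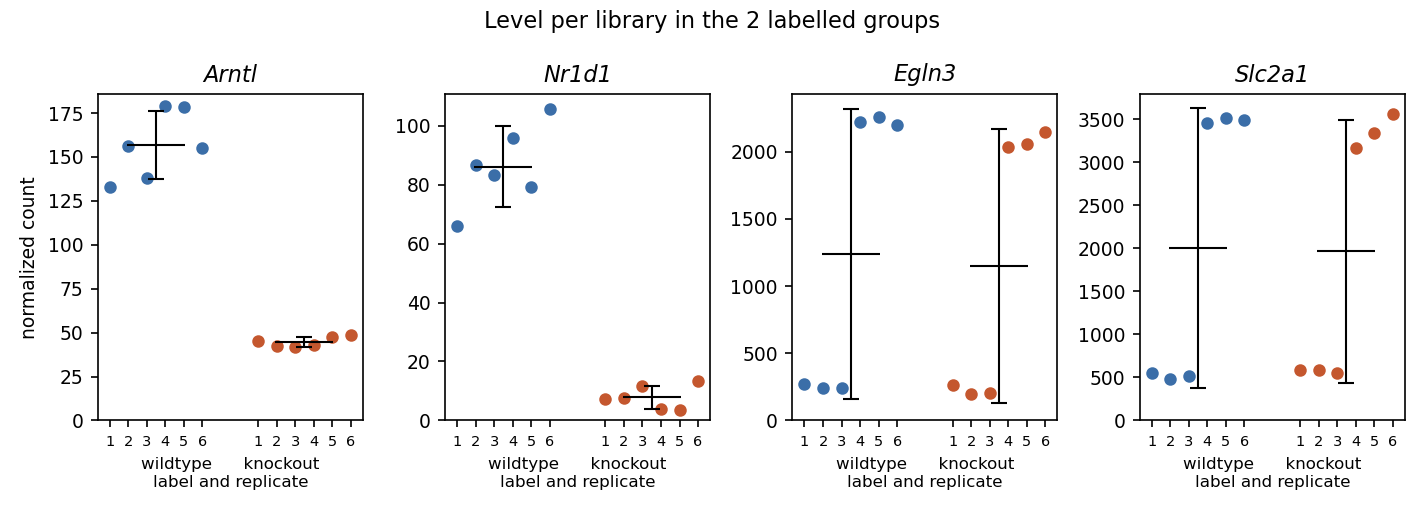
Normalized counts (vertical axes, from 0) of Arntl, Nr1d1, Egln3 and Slc2a1 in each library (points), by label and replicate number, with the group mean and SD (bars, n = 6). Arntl lay at 133 to 179 in the libraries labelled wildtype and at 41.7 to 48.6 in those labelled knockout, whereas Egln3 ranged from 241 to 2258 and from 194 to 2143.

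The main comparison asked which transcripts differed between the libraries labelled Bmal1 knockout and those labelled wildtype. Among genes with a mean of 50 or more, the falls were led by the nuclear receptor gene Nr1d2, 11.1-fold lower, at 209 ± 16.2 normalized counts in the libraries labelled wildtype and 18.3 ± 4.73 in those labelled knockout (SD, n = 6 each). Next came Alpk2, a muscle kinase gene, Fam13a, Ppp1r3a, the muscle glycogen-targeting subunit of protein phosphatase 1, and Myot, which encodes the Z-disc protein myotilin (9.39-, 9.13-, 8.84- and 7.28-fold lower). Apart from Hmga1b, the rises were led by Casq1, which encodes the calcium store protein calsequestrin, from 34.7 ± 7.60 to 187 ± 32.0, Tnnc1, slow and cardiac troponin C, from 257 ± 58.5 to 1257 ± 76.9, and R3hdml, from 26.5 ± 5.95 to 117 ± 9.77. Wfs1, an endoplasmic reticulum membrane protein gene, rose 3.23-fold, and Mymk, the myoblast fusion gene myomaker, rose 2.94-fold.

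In all, 2416 of 12553 genes (19.2%) passed adjusted p 0.05 by limma, 1277 higher and 1139 lower in the libraries labelled knockout. Of these, 115 rose and 281 fell at least 2-fold. All 6 values of one label lay above all 6 of the other in 1562 genes (12.4%), where chance gives 0.216%. The largest rise among the genes past the threshold, of Hmga1b, rested on 3 libraries: it stood at 18.1, 753, 26.6, 445, 20.3 and 960 normalized counts in knockout replicates 1 to 6 and at 12.7 or less in the libraries labelled wildtype, and its reads can be shared with near-identical copies. When 11 very abundant genes, mostly non-coding, were left out and the rest rescaled to library totals, the median log2 fold change of all genes moved to -0.16 and the calls became 617 higher and 2200 lower. Rises of single genes are accordingly relative to the deposited scale.

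Clock genes moved both ways. Of 4 measured clock activators, Npas2, a paralogue of Clock, rose from 34.0 ± 10.1 to 95.7 ± 11.4 normalized counts (SD, n = 6 each; log2 fold change 1.51, SE 0.19, limma adjusted p = 0.000113), Arntl fell, and Clock and Rora did not pass. Of 16 clock repressors and outputs, 3 rose, 4 fell and 9 did not pass, with the same counts adjusted over the list alone. Cry1, a repressor of the clock activators, rose 2.60-fold (adjusted p = 0.000234), while Nr1d1, Nr1d2, Per3 and Dbp fell 10.7-, 11.1-, 3.65- and 2.48-fold. Nr1d1 stood at 3.90 and 3.38 in knockout replicates 4 and 5, not above the floor of 3 reads there (5.85 and 3.38), so its fold is uncertain. Per3 stood at 74.3 in wildtype replicate 2, against 19.3 to 29.9 in the others of that label. Per2 (log2 fold change 1.00, adjusted p = 0.0454) and Tspan4 (0.43, adjusted p = 0.0346) passed less firmly. Per2 was lost without any of wildtype replicates 1, 2, 4 and 5 or knockout replicates 3, 4, 5 and 6 (adjusted p from 0.0517 to 0.0938), and in 4 other settings. Tspan4 was lost without any of wildtype replicates 1, 2, 3 and 6 or knockout replicates 2, 3, 5 and 6 (from 0.0513 to 0.0759), and in 6 other settings, furthest without the abundant genes (log2 fold change 0.26, adjusted p = 0.151). Of 16 BMAL1 targets, 2 rose and 6 fell, over all genes and adjusted over the list alone. The list was lower by camera (adjusted p = 0.0161), but not with an estimated correlation (adjusted p = 0.0809 with an estimated correlation). The call was also lost with a minimum mean of 50, where the mean log2 fold change went from -0.65 to -0.17 (adjusted p = 0.464), and without the abundant genes (adjusted p = 0.0879).

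Sarcomere genes, which encode the contractile apparatus, changed in 31 of 38 cases, 23 higher and 8 lower, with 23 and 11 adjusted over the list alone. Tnnc1 rose 4.97-fold, while Tcap, the titin-capping protein telethonin, fell from 81.3 ± 18.2 to 18.1 ± 3.60 (log2 fold change -2.10, SE 0.19, adjusted p = 6.71e-06) and Xirp2, an actin-binding muscle protein, fell 3.05-fold. The list was higher by camera (adjusted p = 2.14e-05; adjusted p = 0.302 with an estimated correlation). Of 24 myogenic regulators, 5 rose and 9 fell, with 5 and 11 adjusted over the list alone. Mymk and Des, the intermediate filament gene desmin, rose 2.94- and 2.13-fold. Myf5, a determination factor of muscle precursors, and Msc, a repressor of myogenic factors, fell 6.55- and 5.20-fold. In knockout replicate 4 they stood at 3.90 and 5.85 normalized counts, not above the floor of 3 reads there (5.85). Camera did not call this list in one direction (adjusted p = 0.331). Of 19 muscle atrophy genes, 2 rose and 8 fell, also adjusted over the list alone. Mstn, which encodes the growth inhibitor myostatin, fell 4.51-fold, and Gadd45a fell 1.75-fold (list adjusted p = 0.00965; adjusted p = 0.377 with an estimated correlation). The libraries labelled wildtype held 1 that stood apart, replicate 2, in which 29.6% of genes were at 0, against 13.0% to 21.9% in the others.

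Genes of the ribosome and the respiratory chain rose together. All 46 measured genes of cytosolic ribosomal proteins were higher in the libraries labelled knockout, with a median log2 fold change of 0.48, Rpl35 by 0.78 (SE 0.11) and Rpl14 by 0.69 (SE 0.08). Of 50 nuclear genes of oxidative phosphorylation, 39 rose and none fell, 46 when adjusted over the list alone, with a median of 0.56. Cox7b, a cytochrome c oxidase subunit, went from 326 ± 68.7 to 729 ± 59.0, and Uqcrh, a complex III subunit, from 353 ± 47.2 to 739 ± 40.1 (SD, n = 6 each). Of 13 mitochondrially encoded genes, 10 rose, 11 adjusted over the list alone, with a median of 1.05 and a mean of 1.56. mt-Co2 and mt-Co3 were erratic within labels and did not pass (limma adjusted p = 0.0603 and 0.156). In wildtype replicates 1 to 6, mt-Co2 stood at 0, 0, 0, 379, 473 and 121 normalized counts, and mt-Co3 at 511, 0, 503, 1981, 410 and 0.714. In the libraries labelled knockout they ranged from 154 to 671 and from 512 to 2113. mt-Atp6 rose by 1.85 (SE 0.29), although it overlaps mt-Atp8 and can share reads with nuclear copies of mitochondrial DNA. All 3 lists were called by camera (adjusted p = 1.96e-28, 9.48e-27 and 5.49e-09). None was called with an estimated correlation (adjusted p = 0.156, 0.0809 and 0.051 with an estimated correlation). The mean of the ribosomal list, 0.49, was 0.24 with quantile normalization and stayed past the threshold. In wildtype replicate 2 the mean log2 level was 10.41 for ribosomal protein genes and 8.17 for respiratory chain genes, where the other libraries labelled wildtype had 10.73 to 10.92 and 8.56 to 8.71.

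Other metabolic genes were mixed. Of 26 genes of mitochondrial biogenesis and fatty acid oxidation, 5 rose and 4 fell, also adjusted over the list alone, and the list was not called (adjusted p = 0.570; median log2 fold change 0.09, mean -0.06). Fabp3, the muscle fatty acid-binding protein, rose 2.89-fold, whereas the coactivator genes Ppargc1a and Ppargc1b fell 4.84- and 2.11-fold. Ppargc1a stood at 3.73 in knockout replicate 2, at the floor of 3 reads there. In wildtype replicate 2 it stood at 122, against 36.4 to 62.8 in the others of that label. Of 21 glycolysis genes, 4 rose and none fell, also adjusted over the list alone. Pgam2 and Eno3, the muscle forms of phosphoglycerate mutase and enolase, rose 1.78- and 1.52-fold. The glycolysis call (adjusted p = 0.0106; adjusted p = 0.570 with an estimated correlation) was lost without wildtype replicate 2 (adjusted p = 0.0576), with quantile normalization, where the list mean went from 0.23 to 0.0132 (adjusted p = 0.723), and with library weights, where it was -0.089 (adjusted p = 0.452). The difference was 0.12 to 0.15 without any of wildtype replicates 1, 2 and 3 or knockout replicates 4, 5 and 6. The mean log2 level of the list was spread within labels, at 10.15, 10.12, 10.04, 11.09, 11.08 and 11.07 in wildtype replicates 1 to 6 and 10.44, 10.41, 10.28, 11.26, 11.27 and 11.29 in knockout replicates 1 to 6, so that leaving out any 1 library shifts its group mean. Of 24 genes of cholesterol synthesis, 10 rose and none fell, 12 adjusted over the list alone. Lss and Hsd17b7, enzymes of the sterol pathway, rose 1.58- and 1.75-fold, though neither passed without the abundant genes (adjusted p = 0.0546 and 0.053) (list adjusted p = 8.93e-06; adjusted p = 0.051 with an estimated correlation).

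Interferon-response genes were lower in the libraries labelled knockout, 25 of 42 past the threshold and none higher, 27 adjusted over the list alone, with a median log2 fold change of -0.34. Mx2 and Mx1, genes of the antiviral Mx GTPase family, fell from 303 ± 70.1 to 97.2 ± 14.6 and from 103 ± 31.3 to 42.0 ± 16.5 (SD, n = 6 each). GENCODE M21 lists Mx2 as a polymorphic pseudogene. The list was called by camera (adjusted p = 2.77e-13; adjusted p = 0.051 with an estimated correlation). The 2 labels also differ in the virus received, Cre or empty. Of 37 genes of the integrated stress and unfolded protein responses, 3 rose and 13 fell, 4 and 19 adjusted over the list alone. Chac1, a glutathione-degrading enzyme, and Slc7a11, a cystine transporter, fell 2.19- and 1.89-fold, while Atf5 rose 1.36-fold (list adjusted p = 1.56e-05; adjusted p = 0.051 with an estimated correlation). Among 19 heat shock genes 1 rose and 4 fell, 2 and 7 adjusted over the list alone. Hspa4l fell 2.23-fold, and the rise of Hsp90ab1 (log2 fold change 0.31) turned to -0.06 under quantile normalization. The heat shock call (adjusted p = 0.0321; adjusted p = 0.170 with an estimated correlation) was lost without wildtype replicate 1 (adjusted p = 0.053) and with library weights (adjusted p = 0.0808).

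Genes of the extracellular matrix were higher in 16 of 40 cases and lower in 1, 20 and 1 adjusted over the list alone. Col4a1 and Col4a2, the basement membrane collagens, rose 1.62- and 1.69-fold (list adjusted p = 2.22e-06; adjusted p = 0.192 with an estimated correlation). With quantile normalization the matrix call was lost, the list mean going from 0.26 to 0.0164 (adjusted p = 0.991), and Col4a1 rose by a log2 fold change of 0.31 in place of 0.69. Of 27 antioxidant genes under NRF2, 9 rose and 4 fell, 9 and 5 adjusted over the list alone, with Gstm1, a glutathione transferase, 2.35-fold and Gpx3, a glutathione peroxidase, 1.75-fold higher. That list was not called (adjusted p = 0.0884), except without a filter (adjusted p = 0.0277). Of 31 autophagy genes 7 rose and 1 fell, 10 and 2 adjusted over the list alone, among them the lysosomal proteases Ctsd and Ctsl (1.54- and 1.43-fold higher). The autophagy call (adjusted p = 0.0406; adjusted p = 0.377 with an estimated correlation) was lost without any of wildtype replicates 1, 2 and 3 or knockout replicates 4, 5 and 6 (adjusted p from 0.053 to 0.0875), and with a minimum mean of 50 (0.0928), upper-quartile scaling (0.0512), thinning (0.0549), quantile normalization (0.388), library weights (0.177) and the abundant genes left out, where the mean turned to -0.0507 (0.109). Of 41 cell cycle genes 8 rose and 2 fell, also adjusted over the list alone. The mitotic genes Aurka and Kif23 rose 1.75- and 1.65-fold, and the replication licensing genes Mcm6 and Mcm3 fell 1.78- and 1.39-fold (list adjusted p = 0.0222; adjusted p = 0.464 with an estimated correlation; adjusted p = 0.061 with a minimum mean of 50).

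Smaller or undirected lists completed the set. Of 24 angiogenic factors, 3 rose and 2 fell, also adjusted over the list alone. Igf2 and Igf1, insulin-like growth factors, rose 1.77- and 1.74-fold and Angpt1, angiopoietin 1, fell 1.65-fold (list adjusted p = 0.0884). The angiogenic list was called without a filter (adjusted p = 0.0303), without knockout replicate 1 (adjusted p = 0.047) and without the abundant genes (adjusted p = 0.025), where its mean turned from 0.14 to -0.0232. Of 24 p53 and DNA damage genes, 2 rose and 6 fell, 5 and 7 adjusted over the list alone. The apoptosis gene Bbc3 fell 2.03-fold (list adjusted p = 0.33). Of 28 immediate early genes, 2 rose and 3 fell, also adjusted over the list alone, with Egr1 1.68-fold higher and Gem 2.09-fold lower (list adjusted p = 0.393). Of 19 inflammatory NF-kB genes 1 fell, Tnf, from 16.2 ± 8.36 to 4.55 ± 3.77 (list adjusted p = 0.570). Its fold is uncertain: it stood at 0.824, 1.95 and 2.25 in knockout replicates 1, 4 and 5, below the floor of 3 reads there (2.47, 5.85 and 3.38). In wildtype replicate 2 it stood at 32.5, against 9.28 to 16.1 in the others of that label. Of 20 replication-dependent histone genes, 1 rose and 5 fell, 1 and 6 adjusted over the list alone. Hist1h2bc rose 1.55-fold and Hist1h1c fell 1.84-fold. The histone call (adjusted p = 0.0413; adjusted p = 0.549 with an estimated correlation) was lost without any of wildtype replicates 1, 3 and 5 or knockout replicates 4, 5 and 6 (adjusted p from 0.053 to 0.116), and with a minimum mean of 50 (0.0583), upper-quartile scaling (0.057), quantile normalization (0.087), library weights (0.0814) or the abundant genes left out (0.0767).

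**Figure D2:**
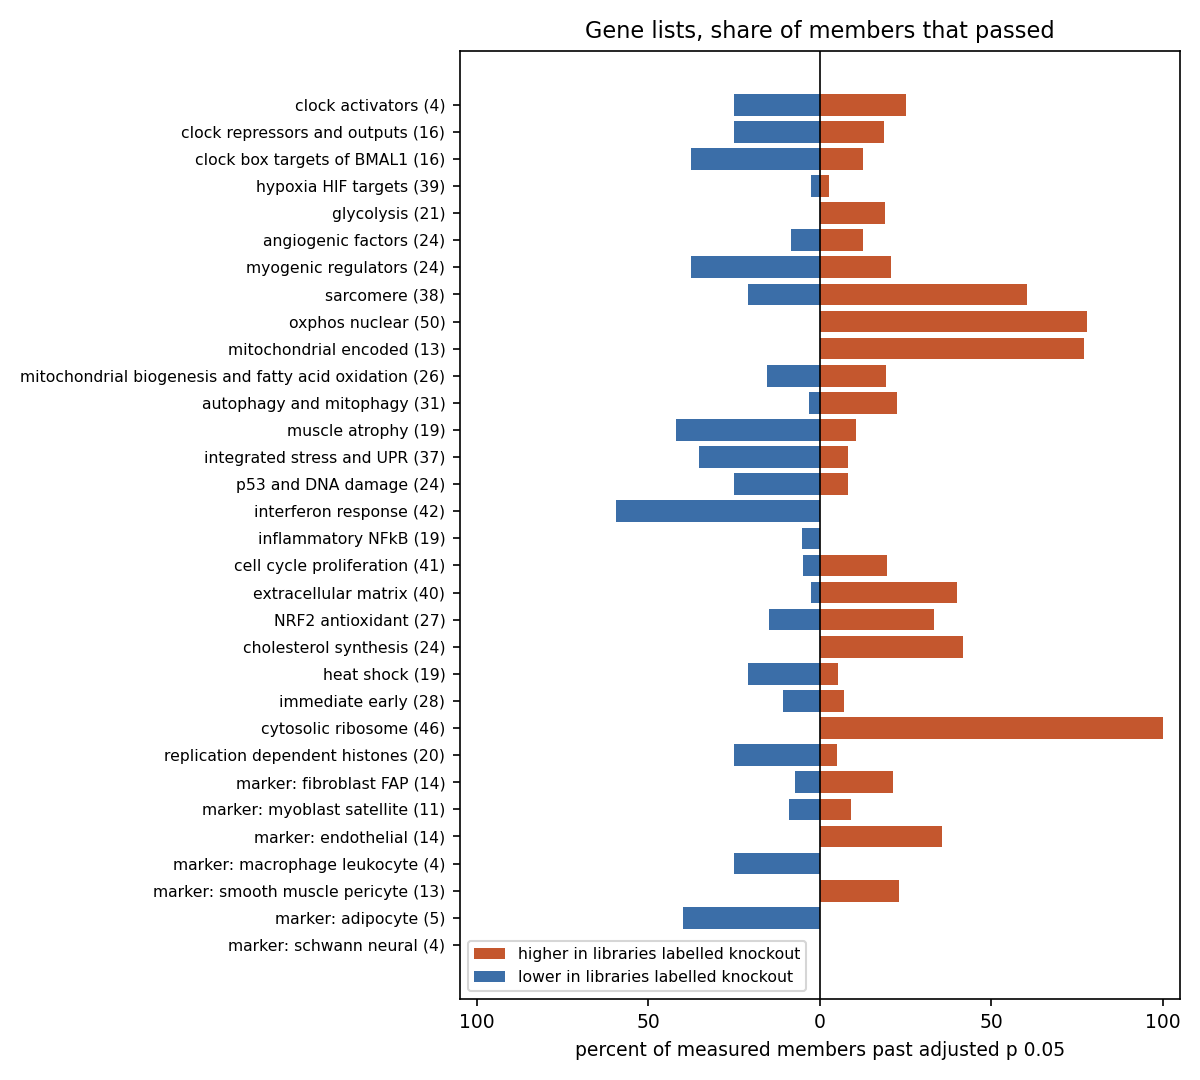
Percent of the measured members of each gene list (number in parentheses) past limma adjusted p 0.05, to the right where higher and to the left where lower in the libraries labelled knockout (n = 6 per label). All 46 ribosomal protein genes and 39 of 50 respiratory chain genes were higher, and 25 of 42 interferon-response genes were lower.

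Markers of other cell types that a primary muscle culture can hold were measured beside these lists. Of 14 endothelial markers, 5 rose and none fell, 11 adjusted over the list alone, with a median log2 fold change of 0.42 (adjusted p = 0.000274; adjusted p = 0.051 with an estimated correlation). Of 14 fibroblast markers, 3 rose and 1 fell, 5 and 1 adjusted over the list alone (adjusted p = 0.040; adjusted p = 0.123 with an estimated correlation). The fibroblast call was lost without wildtype replicate 4 (adjusted p = 0.0811) or knockout replicate 6 (adjusted p = 0.0603), with a minimum mean of 50 (adjusted p = 0.0928), upper-quartile scaling (adjusted p = 0.0594) or quantile normalization (adjusted p = 0.777). It was also lost without the abundant genes (adjusted p = 0.405), where the list mean turned from 0.13 to -0.037. Of 13 smooth muscle and pericyte markers, 3 rose and none fell, also adjusted over the list alone, one of them the muscle gene Des (adjusted p = 0.013; adjusted p = 0.0738 with an estimated correlation; adjusted p = 0.0727 with quantile normalization). Of 11 myoblast markers 1 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.681; median log2 fold change 0.04, mean -0.16). Of 5 adipocyte markers 2 fell, also adjusted over the list alone (adjusted p = 0.148). Of 4 macrophage markers 1 fell, with 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.464). None of 4 Schwann cell markers passed (adjusted p = 0.373), and none of 10 erythroid markers was measured above the minimum.

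**Figure D3:**
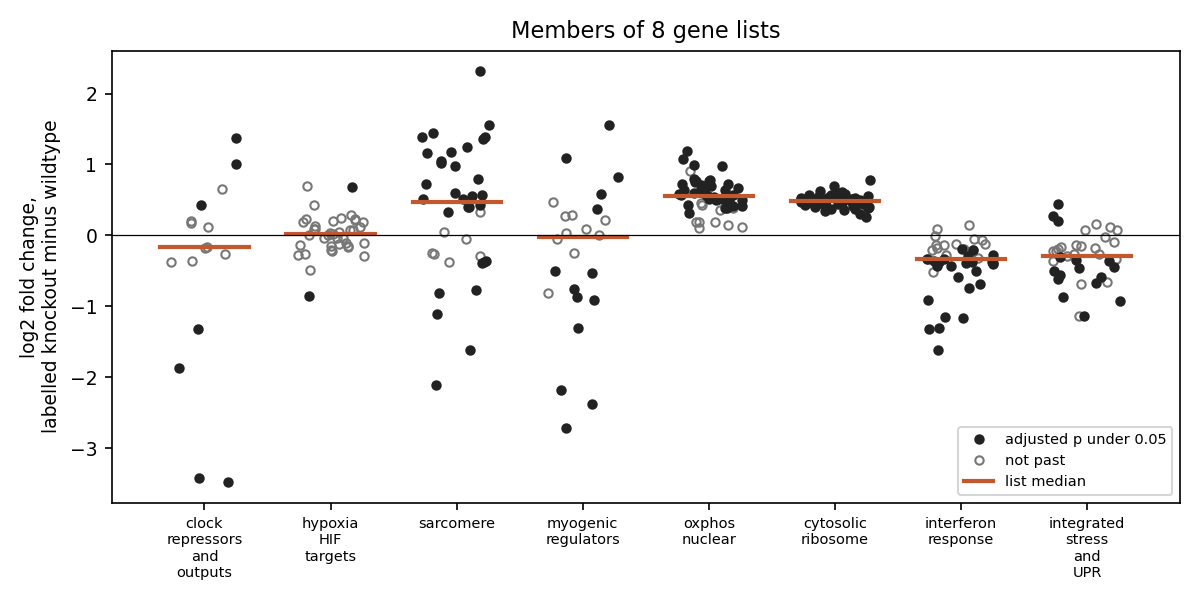
Log2 fold change (labelled knockout minus labelled wildtype) of each measured member of 8 gene lists; filled points passed adjusted p 0.05, open points did not, and the line is the list median. Ribosomal protein genes lay on one side of 0 with a median of 0.48, whereas sarcomere genes reached from -2.10 to 2.31.

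Camera with its preset correlation called 18 of 32 lists, and with an estimated correlation it called 0, with 10 at an unadjusted p under 0.05. Fry, which asks whether the members of a list move on balance one way, called 22. The label of each library is taken as deposited, and since hypoxia genes differed between libraries of the same label, the spread within groups includes that difference.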

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

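Of the tests below, only the one on sarcomere genes and transcript length was written down before its result was seen. In 226 groups of 6 values (106 genes and 7 measures per library, in both labels), 20 had a lowest or highest value far from the rest, where chance gives about 1 in 20 groups, or 11.3 here. Wildtype replicate 2 made up 14 of the 20.

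That library had the fewest reads of its label, 6.38 M (6376584) against 10765961 to 11995291, the highest share of genes at 0, 29.6% against 13.0% to 15.4%, and 14190 genes detected at a common depth against 16156 to 16277. Its normalized counts were high for Per3 (74.3), Mycl (356.2), Ppargc1a (122), Fbxo40 (75.9), Psat1 (1327), Tnf (32.5) and Egr1 (108). They were low for Acadm (127), Dnajb4 (203), Hist1h2bc (240) and Hist1h1c (671). Elsewhere, Dbp was low at 34.7 and Hist1h4i high at 51.6 in wildtype replicate 5. Eno3 was high in knockout replicate 1 (2824), Fabp3 in replicate 4 (314), Fbxo40 in replicate 5 (16.9) and Kif5c in replicate 6 (52.4).

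Hypoxia genes differed widely between libraries of the same label, in both groups. Sequencing depth is argued against: the SD of the hypoxia list mean among libraries labelled wildtype was 0.96 (log2) and stayed at 0.96 after thinning to a common depth. Reads taken by the abundant genes are argued against as well, since the SD was 0.91 without them. A candidate explanation that stays open is another oxygen exposure of some libraries of both labels than their label states. Of the 39 list members, 20 were among the 5% of genes with the widest spread within labels (1.95 expected by chance). This count restates the pattern and decides nothing about it. The list mean was 8.10 to 8.18 in replicates 1 to 3 of both labels and 9.87 to 9.91 in replicates 4 to 6 of both. The 4 conditions of the design text would put both oxygen levels in each genotype. The labels, however, do not say which libraries would be concerned.

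Ribosomal protein and respiratory chain genes were higher in the libraries labelled knockout, and their transcripts are short (median lengths 1124 and 1232 bases against 3449 over the genes tested). Length and GC content are argued against as the whole cause: without their trend the list means still differed by 0.39 and 0.48 (0.49 and 0.56 with it), both past the exact permutation test (p = 0.00216, the smallest it can give). Wildtype replicate 2 is argued against as well, since without it the differences were 0.41 and 0.49 (exact permutation p = 0.00216). Oxygen as labelled in every library is argued against insofar as hypoxia genes report it. Their list mean was 8.10 to 8.18 in replicates 1 to 3 of both labels and 9.87 to 9.91 in replicates 4 to 6 of both. It differed between labels by 0.0167 (95% interval -1.21 to 1.25, against a span of 1.78 among libraries labelled wildtype). That interval is wide because of the split within labels and decides little alone. The labelled genotype and the virus stay open and were not tested apart.

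Sarcomere genes moved both ways, 23 up and 8 down. A different share of muscle cells in the cultures is argued against as the whole cause, since it would move them one way and 8 passed against the majority. Transcripts that fell were longer (median 4785 bases against 2153 for those that rose), yet 7 of the 8 still passed in the same direction once the length and GC trend was removed, so length is argued against as the whole cause. Oxygen as labelled is argued against by the same library levels of the hypoxia list, less so by its wide interval (upper limit 1.25). Which part genotype or virus has in the pattern was not tested.

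For the count of genes, 2 of 100 drawn splits of the 12 libraries gave as many genes, the real one with 2416 among them. The other, with 2464 genes, set replicates 1 to 3 of both labels against replicates 4 to 6 of both, while the remaining 98 gave 0. Those 98 cut across the labels and these replicate sets, so both differences enter their spread. Their 0 therefore does not stand for chance alone. The split with 2464 genes points to a structure of the samples that the labels do not describe, as large as the labelled contrast. For the count of lists, 1 of 100 splits, the real one, gave 18 or more, and the highest other gave 16. Many of the other splits follow the labels in part, but the 45 with 3 libraries of each label on both sides still gave a median of 4 lists and at most 10. Some of these leave replicates 1 to 3 and 4 to 6 uneven: the split with 10 lists did, and the split with 2464 genes gave 8. Camera at its preset correlation thus also called lists where the labels are balanced. Those lists can hold the difference between the replicate sets, so they do not show what it calls by chance.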

How the results depend on the processing

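The alternatives on scale without the abundant genes, on thinning and on length were chosen after seeing the data. Of 89 named or label-check genes past the threshold, 73 stayed past it in the same direction in every alternative that gave them a value. Of 18 lists, 9 stayed past it in every alternative run with the preset correlation of camera. The count of genes past the threshold ranged from 1998 (thinned) to 3381 (library weights), except that a fold threshold left 396 by construction, 115 higher and 281 lower. Without the abundant genes 617 were higher and 2200 lower, because the rescaling moved the median log2 fold change to -0.16. With an estimated correlation camera called 0 lists (10 at an unadjusted p, and 22 by fry). Leaving out 1 library gave 2031 to 2733 genes (most without wildtype replicate 2), 1071 to 1479 higher, 936 to 1254 lower, 15 to 19 lists, an Arntl difference of -1.82 to -1.74 and an SD of the hypoxia list of 0.95 to 0.96.

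Directions turned mainly for genes that had not passed, and the cause was not tested. Clock turned to -0.000796 with upper-quartile scaling. With quantile normalization Hsp90ab1 (past the threshold before) turned to -0.0629, Slc2a1 to -0.15, the hypoxia list to a mean of -0.0837 and the fibroblast list to -0.0024. With library weights Rora became -0.36, Cry2 -0.28, Ciart -0.81, Pdk1 -0.28, Slc2a1 -0.87, Car9 -0.54 and the hypoxia list -0.57. The list was then past the threshold by camera at its preset correlation (adjusted p = 0.0492). Without the abundant genes Clock became -0.13, Rora -0.0929, Tef -0.0483, Slc2a1 -0.12 and Car9 -0.068. The means of the fibroblast (-0.037), autophagy (-0.0507) and angiogenic (-0.0232) lists turned there as well, though not their direction in the camera test. Slc2a1 became -0.0279 with edgeR and -0.0282 with DESeq2. In the camera test the hypoxia list turned direction with a minimum mean of 50 (mean 0.0113) and, like the clock activators (0.0824), without the length trend (0.0291). Leaving out 1 library moved Bhlhe40 from -0.38 to 0.0694, Car9 from -0.18 to 0.42, Ciart from -0.37 to 1.02, Clock from -0.022 to 0.10, Egln3 from -0.49 to 0.21, Per1 from -0.32 to 0.031, Rora from -0.0793 to 0.23, Slc2a1 from -0.25 to 0.32 and the hypoxia list from -0.16 to 0.20. Slc2a1, Car9, Rora and the hypoxia list turned negative without any of wildtype replicates 1 to 3 or knockout replicates 4 to 6. Egln3 turned positive without any of wildtype replicates 4 to 6 or knockout replicates 1 to 3. Each such run leaves replicates 1 to 3 and 4 to 6 uneven in 1 label. No paired analysis was possible because replicate numbers only follow accession order. A fit taking out the difference between replicates 1 to 3 and 4 to 6 was not made, since only the values show these sets. That difference stays in the spread of the main test, so genes and lists not called may still differ between labels. Within each set, glycolysis and autophagy list means were higher in every library labelled knockout than in any labelled wildtype. Histone list means overlapped in replicates 1 to 3.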

Other observations

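Some genes outside the hypoxia list were also among those with the widest spread within labels; the ones named here were picked after their values were seen. Selenbp1, a selenium-binding protein gene, stood at 70.4, 60.4, 54.2, 1552, 1688 and 1343 normalized counts in wildtype replicates 1 to 6 and at 36.3, 27.4, 23.1, 1550, 1563 and 1518 in knockout replicates 1 to 6. Cacna1h, a T-type calcium channel gene, stood at 33.5, 132, 10.3, 440, 357 and 364 in wildtype replicates 1 to 6 and at 12.4, 3.73, 19.5, 345, 415 and 320 in knockout replicates 1 to 6. Limma with the labels as groups called neither (adjusted p = 0.842 for Selenbp1 and 0.671 for Cacna1h), but that spread enters the test, so a difference between labels is not excluded.

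The clock gene Ciart, a repressor of CLOCK and BMAL1 activity, was spread in the same way, at 28.2, 0, 28, 122, 124 and 123 normalized counts in wildtype replicates 1 to 6 and at 15.7, 22.4, 22.2, 127, 125 and 165 in knockout replicates 1 to 6.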
